A study of Mus musculus with 15 samples.

How the data were processed

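RNA of the large intestine was analysed in 15 libraries of 5 groups with 3 libraries each, as the sample labels assign them. Per the submitters' notes, total RNA (90 ng) was depleted of ribosomal RNA before library preparation with a low-input kit, and reads were aligned with STAR 2.4.0j to GRCm38.p4. The deposited values are FPKM (fragments scaled by transcript length and library size) with a lower and an upper bound, 1 library per table, made by the authors. Per the file headers, the columns are those of a Cufflinks gene tracking table. The quantifier's version and settings, any scaling between libraries and the annotation release are not given in the sources used here. Raw reads were not analysed here.

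Part of each table holds annotated genes by Ensembl identifier, and part holds loci assembled separately in each library, whose identifiers are not shared between libraries. Of 38189 annotated identifiers, 37764 are in GENCODE M21, and 82.1% of these have the same start and end there. An assembled locus was given to an annotated gene without a value of its own in that library when the shared span was at least 0.5 of the joint span and each was the other's best match. Loci matched to no gene were not used in the main tests. They were classed as exonic pieces (at least 0.8 of their length in exons of a gene), other loci inside genes, or intergenic loci. An exonic piece was added to a gene, in an alternative fit only, when it was at least 200 bp long and fitted 1 gene, protein-coding genes first. Symbols, positions and gene types are those of GENCODE M21.

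The tables hold no counts. Fragments per locus were estimated from the width of the FPKM interval, which for a Poisson count is set by the square root of the fragments, with an assumed fragment length of 200 bp where an effective length was needed. These estimates give the depth of each library, 25233 to 556461 fragments in protein-coding genes, and served in 1 alternative test. Where an interval is wider than counting allows, the estimate is too low. An FPKM of at least 1 came with an estimate under 0.5 fragments in at least 3 libraries for 1393 of the 11501 genes tested, and in at least 1 library for 5093, so that depth and the voom fit are approximate. Counting error alone is therefore large for genes with few fragments, and an FPKM of a short gene rests on very few. The plan written before the data were examined named a count-based test as the main one if the tables held counts, and the FPKM test otherwise, which was used.

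Values were analysed as log2(FPKM + 1). Genes with a value in all 15 libraries and an FPKM of at least 1 in at least 3 of them were tested, which left 11501. A gene without a value in some library was therefore left out whatever its level, so an untested gene need not be a lowly expressed one. A linear model with 1 mean per group was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, and 8 comparisons were made, 4 with the vehicle, 2 between doses and 2 between agents. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a comparison. Replicate numbers differ between the groups, so nothing pairs the libraries and no pairing was used. An exact test of 3 against 3 cannot go below p = 0.1, and only the model across genes can pass the threshold.

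Gene lists were fixed before the data were examined, 26 of pathways, such as NRF2 targets, and 20 of cell types, such as goblet cells and adipocytes. Each was tested with camera against all other genes, with a preset correlation of 0.01, adjusted over the 46 lists of a comparison, again with an estimated correlation, and with fry. Members were also tested adjusted over the list alone. The score of a list in a library is its mean log2(FPKM + 1) minus that of genes of like mean level, 50 neighbours on each side. The mean correlation of list members within groups was set against 10000 random lists of like level. Similarity between treated groups was set against 100 simulated sets in which groups without change share the 3 vehicle libraries, and overlaps of genes against lists of the same sizes from 100 such sets, taken by the smallest p (20 sets for voom). The share of genes without overlap between groups was set against the mean over all 10 splits of the 6 libraries, which is 10% without ties and less with them. The overlaps of lists of the same sizes and the allowance for ties were added after seeing the data.

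Genes are named by a rule fixed in advance. NRF2 and AHR target genes Nqo1, Gclc, Gclm, Hmox1, Srxn1, Txnrd1, Gsta1, Gstm1, Slc7a11 and Cyp1a1 are always given. Among called genes with a group mean FPKM of at least 1 and without overlap between the groups, the rule takes the 10 largest in each direction against the vehicle and 3 in each direction elsewhere. Where none passes, it takes the 5 (or 3) with the smallest p, as not passing. Up to 4 members are given for each list that passes. Gene models without an established name and small RNA genes are counted and not named by the rule. Since the called genes were all of that kind, they are named as chosen after their values were seen.

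Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values (21560 genes), median-of-ratios scaling on the 1919 genes above 0 in all libraries, quantile normalization, array weights, a fit of only the 2 groups compared, camera with an estimated correlation, and leaving out each library in turn. Chosen after seeing the data were the addition of exonic pieces to genes (11533 genes tested), estimated fragments with voom, leaving out the 3 libraries with over 20% of fragments in intergenic loci, median-of-ratios scaling together with an estimated correlation, and, for NRF2 targets, leaving out the 1393 genes with wide intervals. All alternatives for the similarity between treated groups other than leaving out libraries were also chosen then. The fit without the 3 libraries keeps vehicle replicate 4 as the only vehicle library, assumed to vary like the others. For each comparison, all 10 splits of the 6 libraries into 3 and 3 were fitted in the same way.

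The tests were checked in 20 simulations, with values drawn from each gene's mean over the 15 libraries and its spread within groups. Changes were added to the cymopol high dose, which was compared with the vehicle. Differences in depth between libraries were not simulated, so the rates below may not hold for the real libraries. Of 100 genes raised by 3 on the log2 scale, 28.5% were called, and of 100 raised by 6, 95.3%. False calls made up 4.42% of calls, and a simulation without change gave 0.05 calls on average. A list of 43 genes shifted by 1 on the log2 scale was called in 20 of 20 simulations, and in 0 of 20 without a shift. The simulated genes were independent of each other, so this cannot show whether the preset correlation suits the real lists. Tables were assembled with Python 3.11.15, and figures were drawn with matplotlib 3.10.9.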

Results

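Transcripts of the large intestine were measured by RNA sequencing in male C57Bl/6 mice aged 4 weeks, in 15 libraries that form 5 groups of 3. The vehicle group received Cremophor EL with 10% DMSO. Cymopol, a brominated hydroquinone known from the green alga Cymopolia barbata, was given at a high dose of 1.4 mmol/kg and at a low dose of 0.3 mmol/kg. A non-polar algal extract was given at a high dose of 1.0 g/kg and at a low dose of 0.3 g/kg. Each mouse received 3 daily gavages, and tissue was taken 12 h after the last. The sources used here do not say whether the 3 libraries of a group come from 3 separate mice. If they do not, the p-values measure only the spread between these samples.

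The libraries differed widely in depth and in the kind of RNA they held, and these differences partly followed the groups. Protein-coding genes held an estimated 288349, 342028 and 302879 fragments in the cymopol high dose and 174939, 556461 and 279964 in the extract high dose (replicates in the order 11, 12, 14 and 21, 23, 25). They held 51766, 226553 and 25233 in vehicle replicates 2, 4 and 5. The extract low dose had 28513, 106747 and 71302 (replicates 26, 27, 29), and the cymopol low dose had 31853, 59575 and 183362 (replicates 33, 34, 35). Fragments assigned to genes made up 8.51%, 34.0% and 46.5% of the vehicle libraries, between 33.3% and 71.7% of each low dose library and between 56.9% and 65.5% of each high dose library. Intergenic loci held 46.5% in vehicle replicate 2, 25.1% in vehicle replicate 5 and 23.5% in extract low dose replicate 26, and at most 16.4% in each of the other 12.

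Listing at 0 was common even among housekeeping genes. Of 36 ribosomal protein genes, 5, 2 and 6 were listed at 0 in the vehicle libraries, 8 in extract low dose replicate 26 and 10 in cymopol low dose replicate 33, while the high dose libraries had at most 1. A listing at 0 in these libraries is therefore given as such and not as absence of the transcript. Of the 11501 genes tested, 27.1% to 51.2% were listed at 0 in the vehicle libraries and 5.74% to 13.1% in the high dose libraries. The highest correlation between any pair of libraries was 0.730, across genes.

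**Figure D1:**
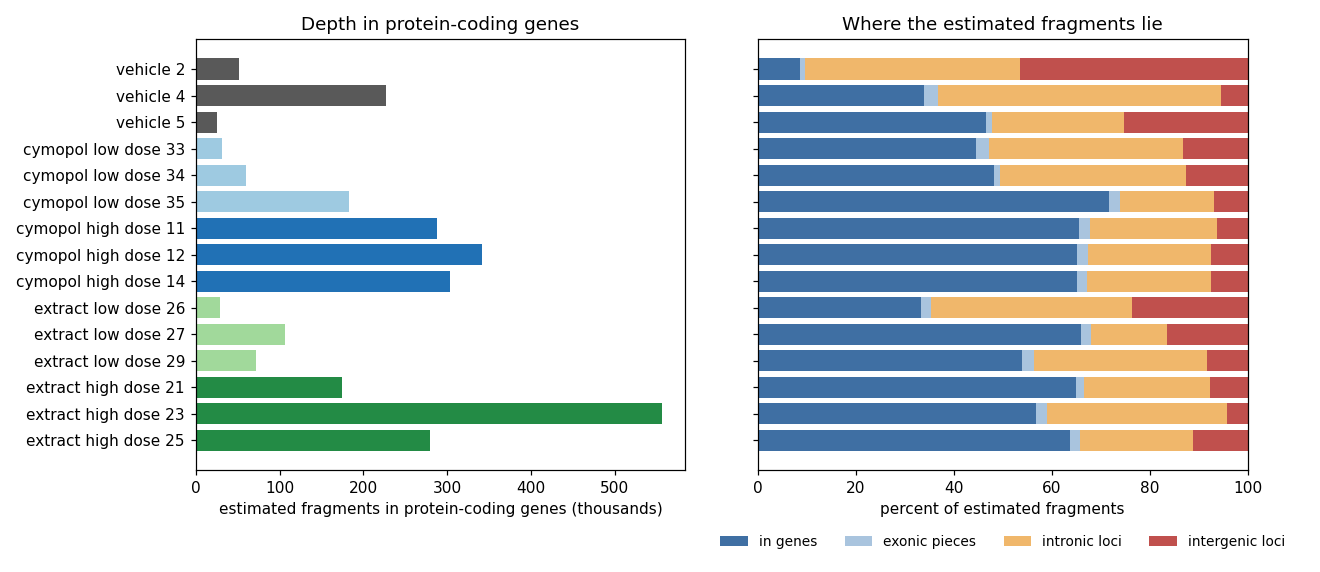
Estimated fragments in protein-coding genes (bars, starting at 0) and the percentage of estimated fragments in genes, in intergenic loci and elsewhere (stacked bars), for each of the 15 libraries. The high dose libraries hold 174939 to 556461 fragments in protein-coding genes, and vehicle replicates 2 and 5 hold 51766 and 25233.

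All differences between groups are differences of mean log2(FPKM + 1), called log2 differences, and they are no fold changes where a group is listed at 0. The median log2 difference over all genes was 0.81 for the cymopol high dose against the vehicle, 0.23 for the cymopol low dose, 0.71 for the extract high dose and -0.14 for the extract low dose. Between doses it was 0.59 for cymopol and 0.89 for the extract. Between agents it was 0.11 at the high doses and 0.39 at the low doses. Median-of-ratios scaling brought these medians to between -0.01 and 0.30. Gene groups are therefore described relative to the mean of all genes in the same comparison. The camera test used a preset correlation of 0.01 between genes. Within groups the adipocyte markers had a mean correlation of 0.553, and random lists of like level had a median of 0.355. These values are far above the preset, so adjusted p from camera with the preset may be too small. Of the 34 camera calls over 368 tests, 1 remained with a correlation estimated from the data, and fry gave 0 calls after adjustment. The 1 that remained was that of mt-Nd6 between the high doses (adjusted p = 0.0332), a list of 1 gene with no correlation between genes to estimate, so it was not tested in this way.

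The comparison of the extract high dose with the vehicle addressed the response to the mixture. NRF2 targets had its smallest adjusted p by camera with the preset correlation, though not the largest difference or the smallest adjusted p with an estimated correlation. NRF2 is the transcription factor that induces antioxidant and detoxifying enzymes under electrophilic stress. The 43 measured NRF2 targets rose relative to all genes, with a mean log2 difference of 1.95 (SD over members 1.24), 1.22 above the mean of all genes. The log2 difference was above 0 for 40 of the 43, but the median of all genes was itself 0.71. The camera test gave adjusted p = 1.03e-05, and adjusted p = 0.906 with an estimated correlation. The share of fragments in genes moved with the list, at 56.9% to 65.0% in the extract high dose and 8.51% to 46.5% in the vehicle. Adjusted over the list alone, 7 members passed, namely Akr1b8, Gsta4, Nqo1, Hmox1, Cbr3, Gclc and Gstm3, and 0 passed over all genes.

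Nqo1 (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206 on GRCm38), a quinone reductase, had 22.4, 7.45 and 8.03 FPKM in the extract high dose and 0.167, 0 and 0 in the vehicle. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), heme oxygenase, had 23.0, 5.10 and 2.96 FPKM and was listed at 0 in the 3 vehicle libraries. Gclc (ENSMUSG00000032350, chromosome 9, 77754535 to 77794485), the catalytic subunit of glutathione synthesis, had 411, 14.9 and 34.5 FPKM against 0.253, 17.1 and 0. The aldo-keto reductase Akr1b8 had 25.0 ± 9.70 FPKM (SD, n = 3) against 1.26, 0 and 0. The carbonyl reductase Cbr3 had 45.4 ± 21.4 FPKM (SD, n = 3) against 0, 0 and 15.4. Gstm1, a glutathione transferase, had 95.2 ± 12.4 FPKM against 14.1 ± 11.8 (SD, n = 3 each), a log2 difference of 3.12 ± 1.31 (SE) with an adjusted p of 0.382 over all genes. Srxn1 differed by 2.69, Gsta1 by 2.48, Txnrd1 by 2.37 and Gclm by 1.91 on the log2 scale, and these 4 did not pass. Slc7a11 reached at most 0.517 FPKM in any library and Cyp1a1 at most 1.74, both under the filter.

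**Figure D2:**
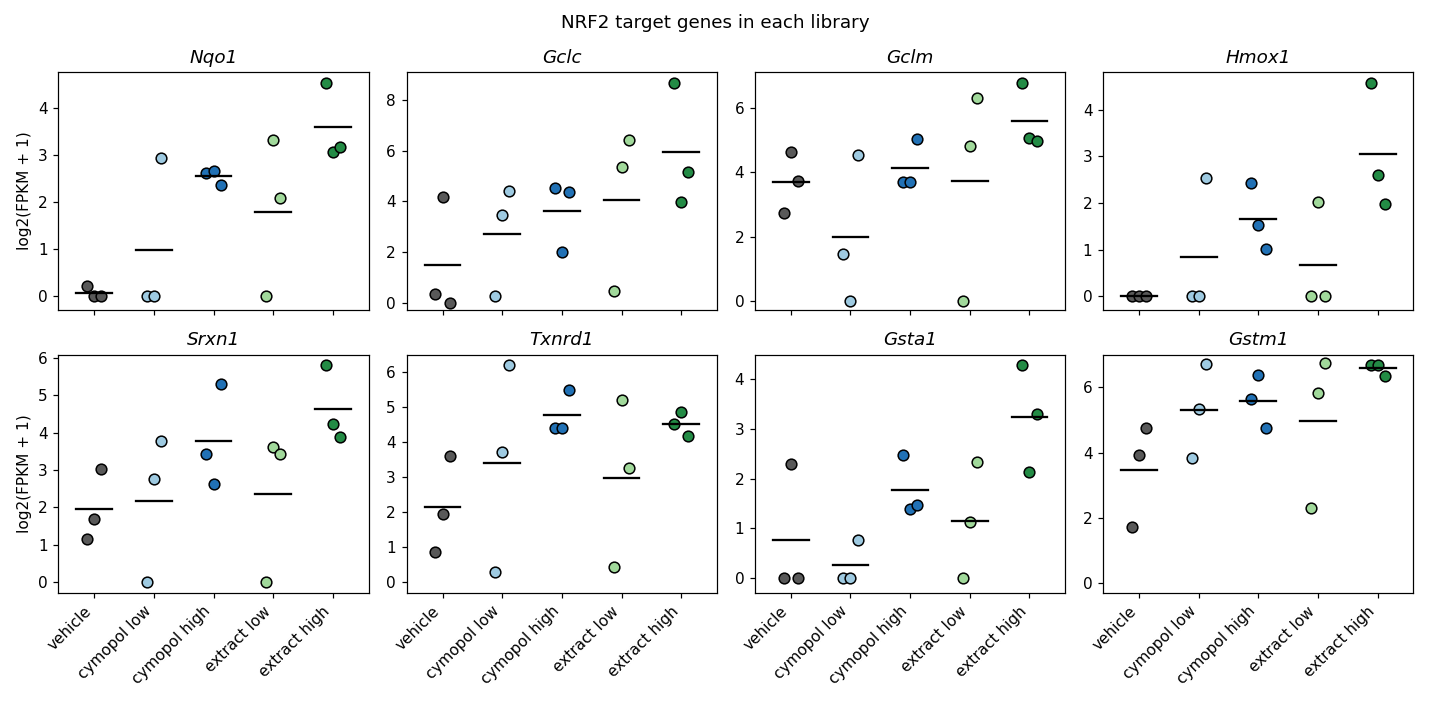
Values of log2(FPKM + 1) of 8 NRF2 target genes in each group, where a point is a library and a line is the mean of 3 libraries. Nqo1 lies at 7.45 FPKM or more in the extract high dose, between 4.19 and 5.31 in the cymopol high dose and at most at 0.167 in the vehicle.

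Genes of energy metabolism and of secretory epithelium rose with the extract high dose relative to all genes. The 30 measured nuclear genes of oxidative phosphorylation had a mean log2 difference of 2.03, 1.30 above all genes (adjusted p = 0.000111, and adjusted p = 0.948 with an estimated correlation). Ndufa5 and Ndufv2, subunits of complex I, passed adjusted over the list alone and were listed at 0 in all vehicle libraries, with 11.4, 11.7 and 5.06 FPKM and 11.3, 9.74 and 6.41 FPKM in the extract high dose. The 9 goblet cell markers stood 1.69 above all genes (mean 2.42, adjusted p = 0.00640, and adjusted p = 0.906 with an estimated correlation). Tff3, the trefoil peptide of goblet cells, passed adjusted over the list alone, with 55.0, 216 and 55.5 FPKM against 0.406, 8.42 and 0. The 14 tight junction genes stood 0.95 above all genes (adjusted p = 0.0379, and adjusted p = 0.948 with an estimated correlation), with 0 members passing. The 36 ribosomal protein genes stood 0.91 above (adjusted p = 0.0379, and adjusted p = 0.988 with an estimated correlation), also with 0 members passing. These groups moved with the share of fragments in genes, which was at least 56.9% in the extract high dose and at most 46.5% in the vehicle.

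Immune, lipid synthesis and fat cell genes were lower relative to all genes in the extract high dose. The 5 B and plasma cell markers had a mean log2 difference of -1.62, that is -2.35 relative to all genes (adjusted p = 0.000278, and adjusted p = 0.750 with an estimated correlation). The 4 T and NK cell markers stood at -1.90 relative to all genes (adjusted p = 0.00142, and adjusted p = 0.750 with an estimated correlation). The 5 MHC class II genes stood at -2.15 (adjusted p = 0.00142, and adjusted p = 0.904 with an estimated correlation). Vehicle replicate 4 carried the high values of these 3 groups. Cd74, the invariant chain, had 1.02, 325 and 7.36 FPKM in vehicle replicates 2, 4 and 5, Fcer2a had 1.05, 179 and 0, and Trbc2 had 0, 32.0 and 0. In the extract high dose Cd74 had 2.74, 13.4 and 4.10 FPKM. The interval of Cd74 was wider than counting allows in some of these libraries. Its estimate was 0.0313 and 0.0464 fragments in vehicle replicates 2 and 5 and 0.12 in extract high dose replicate 21, against 543 in vehicle replicate 4. The 14 genes of fatty acid synthesis had a mean of -0.41, that is -1.14 relative to all genes (adjusted p = 0.00186, and adjusted p = 0.906 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, had 13.8, 7.87 and 7.46 FPKM against 4.40, 305 and 54.0. The 11 adipocyte markers had a mean of -0.16, that is -0.89 relative to all genes (adjusted p = 0.0211, and adjusted p = 0.948 with an estimated correlation). mt-Nd6 (ENSMUSG00000064368, mitochondrial genome, 13552 to 14070) was the only mitochondrially encoded gene tested, from a list of 13. The others lacked a value in some library or did not reach the FPKM filter. mt-Nd6 was listed at 0 in all extract high dose libraries, against 40.9, 29.8 and 0 FPKM. Whether the assignment of fragments to assembled loci contributed to these listings at 0 was not tested. As a list of 1 gene mt-Nd6 gave adjusted p = 0.0176, and adjusted p = 0.655 in the run with an estimated correlation. None of the members of these 5 longer lists passed, adjusted over the list alone or over all genes.

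Several of these calls ended when a single library was left out, which can come from a smaller difference or from fewer libraries alone. Without vehicle replicate 4 the calls ended for MHC class II (adjusted p = 0.433), fatty acid synthesis (0.149), tight junction (0.181), mt-Nd6 (0.0588), B and plasma cells (0.0845), T and NK cells (0.172) and adipocytes (0.519). Without vehicle replicate 2 they ended for tight junction (0.123), mt-Nd6 (0.362), ribosomal proteins (0.576), goblet cells (0.0604) and adipocytes (0.0583). The ribosomal call also ended without vehicle replicate 5 (0.0549), extract high dose replicate 21 (0.0644) or replicate 23 (0.155), the tight junction call without replicate 21 (0.0840) or 25 (0.0779), and the adipocyte call without replicate 23 (0.231). Median-of-ratios scaling ended the calls of tight junction (0.322), ribosomal proteins (0.204), mt-Nd6 (0.110) and adipocytes (0.0707). Without the 3 libraries with over 20% of fragments in intergenic loci, the calls of tight junction (0.103), mt-Nd6 (0.0686) and goblet cells (0.0798) ended, and the mean of the ribosomal protein genes turned to -0.06 (0.847). In that fit vehicle replicate 4 is the only vehicle library. Quantile normalization ended the calls of mt-Nd6 (0.122) and adipocytes (0.0572), and voom that of fatty acid synthesis (0.124). The NRF2 and oxidative phosphorylation calls held without any single library, with adjusted p of at most 0.00423 for NRF2.

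Among single genes, 1 of the 11501 was called in the extract high dose against the vehicle by limma. It was Snord11 (ENSMUSG00000089093, chromosome 1, 59704790 to 59704873), a small nucleolar RNA gene named here after its values were seen. It had 97.3, 151 and 31.0 FPKM and was listed at 0 in the other 12 libraries (adjusted p = 8.57e-05). These values came from an estimated 1.99, 6 and 1 fragments, and the call ended when only these 2 groups were fitted (adjusted p = 0.267) and with voom (0.987). At an unadjusted p under 0.05 there were 1332 genes, 1215 higher and 117 lower, and after median-of-ratios scaling 813 higher and 327 lower. The groups did not overlap for 19.8% of genes, 2224 higher and 52 lower, where chance gives 9.07%, ties at 0 taken into account. The value for chance takes the libraries as alike, so it leaves out the differences in depth between them. The voom fit of estimated fragments called 140 genes, 36 higher and 104 lower, and Snord11 was not among them. The genes with the smallest p that did not pass were Rnf215, Tmem70, Eif2b2, Tnni1 and Ost4 among the higher and Sh3gl3, Ifi208, Nop56, Map4k2 and Tead2 among the lower. Sh3gl3 had 0.725, 0 and 0 FPKM against 2.46, 10.4 and 12.7, a log2 difference of -2.76 ± 0.67 (SE) with an adjusted p of 0.238. Leaving out vehicle replicate 2 gave 8 called genes, and leaving out vehicle replicate 4 gave 2.

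**Figure D3:**
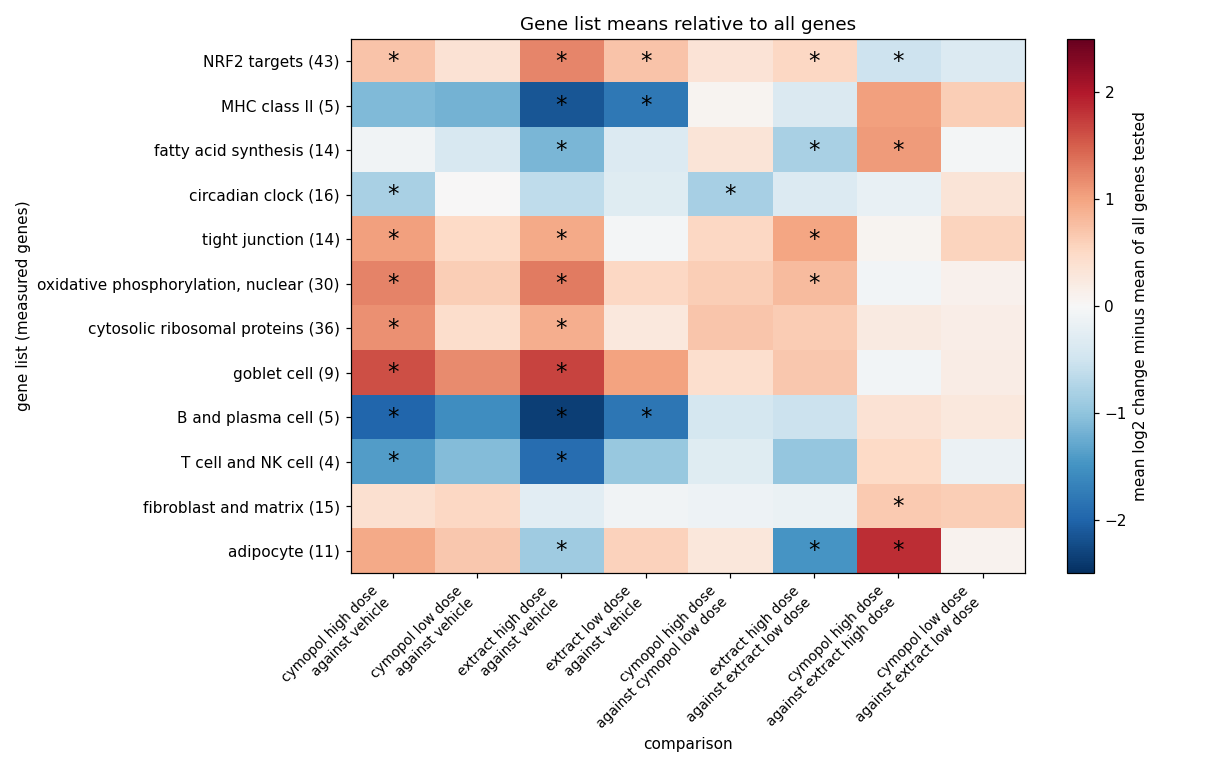
Mean log2 difference of 12 gene lists minus the mean of all genes (colour) in the 8 comparisons, with a star where camera gave an adjusted p under 0.05. NRF2 targets carry 1.22 for the extract high dose against the vehicle, and adipocyte markers carry 1.84 for the cymopol high dose against the extract high dose.

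Cymopol at the high dose against the vehicle addressed the response to the isolated compound. NRF2 targets rose relative to all genes here too, with a mean log2 difference of 1.54 (SD over members 1.08), 0.71 above all genes. Of the members, 39 of 43 lay above 0, but the median of all genes was itself 0.81. The camera test gave adjusted p = 0.0288, and adjusted p = 0.991 with an estimated correlation. The share of fragments in genes moved with the list here as well, at 65.2% to 65.5% against at most 46.5% in the vehicle. Gpx2, a glutathione peroxidase of gut epithelium, was the 1 member that passed adjusted over the list alone, with 14.3, 25.9 and 11.3 FPKM against 0.447, 0 and 0, and 0 members passed over all genes. The intervals of Gpx2 and Txnrd1 are wider than counting allows, so that no number of fragments can be estimated for them. Without the genes with such intervals the NRF2 call ended (38 members, mean 1.49, adjusted p = 0.0685). Nqo1 had 4.89 ± 0.606 FPKM (SD, n = 3) against 0.167, 0 and 0. Hmox1 had 4.38, 1.88 and 1.02 FPKM against 0 in all 3 vehicle libraries, and Gclc had 22.2, 3.02 and 19.7 against 0.253, 17.1 and 0. The log2 differences that did not pass were 2.62 for Txnrd1, 2.13 for Gstm1, 1.83 for Srxn1, 1.01 for Gsta1 and 0.45 for Gclm. The NRF2 call ended without vehicle replicate 2 (adjusted p = 0.117), vehicle replicate 4 (0.390), cymopol high dose replicate 11 (0.137) or replicate 14 (0.0768). It also ended with median-of-ratios scaling (0.0668), a pseudocount of 0.1 (0.119) and array weights (0.0587).

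Respiratory chain, ribosomal, tight junction and goblet cell genes rose relative to all genes with the cymopol high dose. Oxidative phosphorylation genes had a mean log2 difference of 2.07, 1.24 above all genes (adjusted p = 0.000678, and adjusted p = 0.991 with an estimated correlation). Its 3 members past the threshold adjusted over the list alone were Cox5a with 48.2, 78.8 and 76.7 FPKM against 0.494, 12.4 and 0, and Ndufa4 and Ndufa5, both listed at 0 in the vehicle. Goblet cell markers stood 1.62 above all genes (adjusted p = 0.0288), tight junction genes 1.02 above (0.0288) and ribosomal protein genes 1.14 above (0.00908). These 3 lists had adjusted p = 0.991 with an estimated correlation. Tff3 with 105 ± 33.2 FPKM (SD, n = 3) and Spink4 with 98.8, 99 and 29.6 FPKM passed adjusted over the list alone, and the vehicle libraries had 0.406, 8.42 and 0 FPKM and 0, 0 and 45.5 FPKM. None of the tight junction or ribosomal protein members passed. The share of fragments in genes, 65.2% to 65.5% here and at most 46.5% in the vehicle, moved with these groups. Without vehicle replicate 2 the calls ended for tight junction (0.117), ribosomal proteins (0.283) and goblet cells (0.121), and without vehicle replicate 4 for tight junction (0.210) and goblet cells (0.0723). Further endings came without cymopol high dose replicate 11 for goblet cells (0.0564), without replicate 12 for ribosomal proteins (0.0627) and goblet cells (0.0627), and without replicate 14 for tight junction (0.12). Median-of-ratios scaling ended the tight junction (0.285) and ribosomal (0.0534) calls, and the fit without the 3 libraries with over 20% intergenic fragments ended those of tight junction (0.107), ribosomal proteins (0.888) and goblet cells (0.147).

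Lymphocyte and circadian clock genes were lower relative to all genes in the cymopol high dose. B and plasma cell markers had a mean log2 difference of -1.15, that is -1.99 relative to all genes (adjusted p = 0.00380), and T and NK cell markers -0.56, that is -1.40 (0.0288). The 16 clock genes had a mean of 0.02 and a median of -0.20, that is -0.82 relative to the mean of all genes (adjusted p = 0.0288). The sign of the mean therefore differs from that of the median and of the test. All 3 lists had adjusted p = 0.991 with an estimated correlation and 0 members past the threshold. The share of fragments in genes differed along with them, at 65.2% to 65.5% here and at most 46.5% in the vehicle. Pax5 had 0, 6.79 and 0 FPKM against 0, 60.3 and 0.407 in vehicle replicates 2, 4 and 5. Nr1d1, a repressor of the clock, had 0.934, 2.32 and 3.21 FPKM against 0, 13.8 and 20.4. Without vehicle replicate 4 the calls of B and plasma cells (0.390) and of T and NK cells (0.673) ended. The T and NK cell call also ended without cymopol high dose replicate 11 (0.104) or 14 (0.0743) and with median-of-ratios scaling (0.245), and the clock call without vehicle replicate 2 (0.190) or cymopol high dose replicate 12 (0.0627). Quantile normalization (0.0753) and voom (0.0833) ended the T and NK cell call, and voom (0.633) and the fit without the 3 libraries with over 20% intergenic fragments (0.364) ended the clock call.

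Single genes called in the cymopol high dose against the vehicle were 2, both higher, and both are gene models named here after their values were seen. Gm23455 (ENSMUSG00000065265, chromosome 9, 15316489 to 15316588), a small nucleolar RNA gene inside Taf1d, had 148, 168 and 82.1 FPKM from an estimated 11, 9 and 5 fragments and was listed at 0 in the vehicle (adjusted p = 0.0336). Gm11973 (ENSMUSG00000086839, chromosome 11, 6475425 to 6493535) is annotated as antisense and overlaps Purb, and without strand information its signal cannot be assigned to it with certainty. It had 62.5, 25.9 and 4.03 FPKM from an estimated 29.3, 10.2 and 2.61 fragments, against 0.759, 0 and 0 (adjusted p = 0.0460). For Gm23455 and Gm11973 in that order, the calls ended with median-of-ratios scaling (0.0807 and 0.407), without the filter on low values (0.122 and 0.161) and when only these 2 groups were fitted (0.237 and 0.255). They also ended without vehicle replicate 4 (0.102 and 0.167), vehicle replicate 5 (0.0679 and 0.154), or cymopol high dose replicate 11 (0.0534 and 0.0534) or 12 (0.104 and 0.0884). The Gm11973 call ended as well with a pseudocount of 0.1 (0.0824), quantile normalization (0.292), array weights (0.0732) and without the 3 libraries with over 20% intergenic fragments (0.0544). At an unadjusted p under 0.05 there were 1517 genes, 1430 higher and 87 lower, and after median-of-ratios scaling 762 higher and 260 lower. The groups did not overlap for 19.9% of genes, 2243 higher and 42 lower, where chance gives 9.0% with differences in depth left out. The voom fit called 121 genes, 29 higher and 92 lower, and neither gene was among them (0.413 and 0.426). Among genes that did not pass, the smallest p belonged to Crip1, Rarres2, Ccl25, Plpp2 and Mrps21 (higher) and to Nop56, Sh3gl3, Pim2, Map4k2 and Tead2 (lower). Rarres2, which encodes the chemoattractant chemerin, had 20.1, 20.5 and 49.1 FPKM and was listed at 0 in the vehicle (adjusted p = 0.154). Leaving out vehicle replicate 2 gave 8 called genes, and leaving out vehicle replicate 4, vehicle replicate 5 or cymopol high dose replicate 12 gave 0.

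In the low doses against the vehicle, NRF2 targets passed for the extract and not for cymopol. With the extract low dose the list had a mean log2 difference of 0.52 (SD over members 0.989), 0.71 above all genes, and rose relative to them (adjusted p = 0.00589, and adjusted p = 0.987 with an estimated correlation). Of its 43 members, 33 lay above 0, and 0 passed adjusted over the list alone or over all genes. Nqo1 had 0, 8.96 and 3.23 FPKM, Gclc 0.376, 39.6 and 84.1, and Cbr3 0.965, 34.7 and 61.2, where the first value is that of replicate 26. This call ended without vehicle replicate 2 (0.10), vehicle replicate 4 (0.121), extract low dose replicate 27 (0.201) or replicate 29 (0.169). The mean fell to 0.058, 0.094 and 0.040 without vehicle replicate 2 and extract low dose replicates 27 and 29. It rose to 0.74, 0.76 and 1.43 without vehicle replicates 4 and 5 and extract low dose replicate 26. Fragments in genes made up 33.3%, 66.0% and 53.9% of the extract low dose libraries and 8.51%, 34.0% and 46.5% of the vehicle libraries. With the cymopol low dose the mean was 0.61, that is 0.37 above all genes, and camera did not pass (adjusted p = 0.275, and adjusted p = 0.930 with an estimated correlation). Without the filter on low values camera with the preset correlation passed, at a mean of 0.59 (adjusted p = 0.0439). Nqo1 had 0, 0 and 6.64 FPKM and Gclc 0.207, 10.2 and 20.5. The NRF2 difference between the low doses gave adjusted p = 0.270, with a mean of 0.09 for cymopol against the extract, that is -0.34 relative to all genes. The list was lower in the cymopol low dose there with median-of-ratios scaling (0.00776), with voom (0.0160) and without the 3 libraries with over 20% intergenic fragments (0.000813), and did not pass with quantile normalization (0.0711). With an estimated correlation it did not pass either, with adjusted p = 0.983 and, after median-of-ratios scaling, 0.639.

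Other groups in the low doses were few. With the extract low dose, B and plasma cell markers had a mean of -2.00, that is -1.81 relative to all genes (adjusted p = 0.0183), and MHC class II genes -1.98, that is -1.79 (0.0497). Both had adjusted p = 0.987 with an estimated correlation. Fcer2a, the low-affinity IgE receptor of B cells, passed adjusted over the list alone and was listed at 0 in all extract low dose libraries, against 1.05, 179 and 0 FPKM. The B cell call ended without vehicle replicate 4 (0.429), extract low dose replicate 27 (0.340) or 29 (0.0880). The MHC class II call ended without vehicle replicate 4 (0.938) or extract low dose replicate 27 (0.489). Median-of-ratios scaling gave 0.0575 and 0.0738 for them. With the cymopol low dose, 0 of the 46 lists passed camera.

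At the level of single genes, limma called 0 in either low dose against the vehicle. The unadjusted p was under 0.05 for 654 genes with cymopol and for 449 with the extract, voom called 0 in both, and non-overlapping groups made up 4.72% and 2.67% of genes, where chance gives 7.48% and 7.38%. Without vehicle replicate 2 the counts were 9 and 5. Leaving out vehicle replicate 5 gave 8 for the extract, and leaving out vehicle replicate 4, cymopol low dose replicate 33 or replicate 34 gave 1, 1 and 2 for cymopol. The smallest p in the cymopol low dose belonged to Htra2, Rarres2, Thumpd3, Prkar1b and Lrrc6 among the higher and to Sh3gl3, Pim2, Tmem131l, Pde3b and Rapgef4 among the lower. In the extract low dose it belonged to Tma7, Hmg20b, Atpaf2, Atp5mpl and Ift20 and, lower, to Sh3gl3, Rapgef4, Tead2, Tmtc4 and Tmem131l. Rarres2 had 15.1, 51.9 and 32.8 FPKM in the cymopol low dose, and Tma7 had 15.3, 16.5 and 15.3 in the extract low dose against 0.274, 0 and 0. None of these passed.

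The high doses were compared directly to ask where the isolated compound and the mixture differ. Their doses, 1.4 mmol/kg and 1.0 g/kg, are in different units and are not matched. NRF2 targets were lower in the cymopol high dose relative to all genes, with a mean log2 difference of -0.41 (SD over members 0.762), that is -0.51 relative to all genes, and 15 of 43 above 0. The camera test gave adjusted p = 0.00176, and adjusted p = 0.966 with an estimated correlation. Hmox1 had 4.38, 1.88 and 1.02 FPKM with cymopol and 23.0, 5.10 and 2.96 with the extract, and Nqo1 had 5.15, 5.31 and 4.19 against 22.4, 7.45 and 8.03. The NRF2 call ended without cymopol high dose replicate 12 (0.295) or extract high dose replicate 21 (0.141).

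Fat cell, lipid synthesis and connective tissue genes were higher in the cymopol high dose than in the extract high dose. All 11 adipocyte markers had a log2 difference above 0, with a mean of 1.94 (SD over members 0.680), 1.84 above all genes (adjusted p = 4.55e-09, and adjusted p = 0.552 with an estimated correlation). Plin1, the lipid droplet protein perilipin, had 16.7 ± 6.95 FPKM against 1.08 ± 0.990 (SD, n = 3 each), and the adipokine Cfd had 153, 145 and 77.3 FPKM against 45.8, 12.7 and 8.82. Fatty acid synthesis genes stood 1.06 above all genes, with 14 of 14 above 0 (adjusted p = 7.85e-05, and adjusted p = 0.966 with an estimated correlation). Fasn, the fatty acid synthase, had 53.1, 51.1 and 25.1 FPKM against 18.3, 6.48 and 6.18. The 15 fibroblast and matrix genes stood 0.66 above all genes, with 15 of 15 above 0 (adjusted p = 0.00454, and adjusted p = 0.966 with an estimated correlation). None of the members of these 4 lists, NRF2 included, passed adjusted over the list alone or over all genes. The share of fragments in genes was 65.2% to 65.5% in the cymopol high dose. It was lower in extract high dose replicates 21, 23 and 25, at 65.0%, 56.9% and 63.8%, and clearly so only in replicate 23. The fibroblast call ended without cymopol high dose replicate 12 (0.306) or extract high dose replicate 25 (0.0643), and the adipocyte call held without any single library, with an adjusted p of at most 0.000460.

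**Figure D4:**
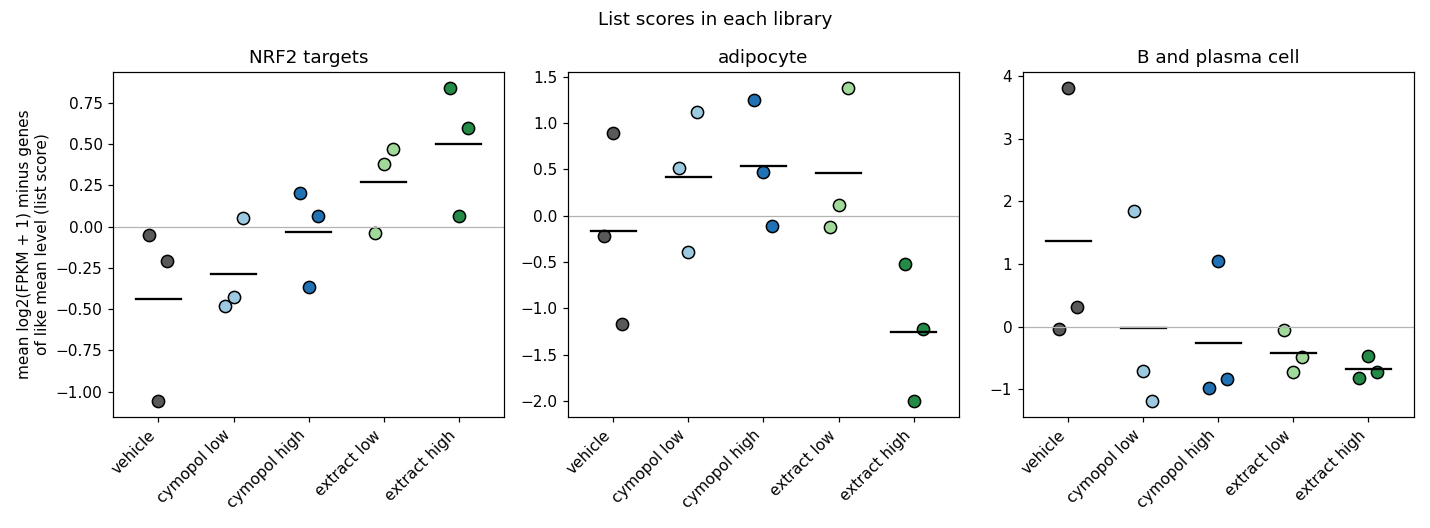
Score of NRF2 targets, adipocyte markers and B and plasma cell markers in each library, as mean log2(FPKM + 1) over that of genes of like level, where a point is a library. The adipocyte score lies between -0.11 and 1.24 in the cymopol high dose and between -2.00 and -0.52 in the extract high dose, and vehicle replicate 4 has a B and plasma cell score of 3.82.

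mt-Nd6, the only mitochondrially encoded gene tested, had 45.1, 79.7 and 40.9 FPKM in the cymopol high dose and was listed at 0 in the 3 extract high dose libraries. As a list of 1 gene it passed camera (adjusted p = 3.68e-05), but over all genes it did not pass (adjusted p = 0.337). The limma test called 2 genes between the high doses. Gm11973 was higher with cymopol (adjusted p = 0.0161) and listed at 0 in the extract high dose, and Snord11 was higher with the extract (adjusted p = 8.57e-05) and listed at 0 in the cymopol high dose. The Snord11 call, from an estimated 1.99, 6 and 1 fragments, ended with voom (adjusted p of 1.00). The Gm11973 call ended without extract high dose replicate 21 (0.137), 23 (0.247) or 25 (0.231), which left 1 called gene each time. It also ended with a pseudocount of 0.1 (0.0816), without the filter (0.114), with median-of-ratios scaling (0.917), quantile normalization (0.388) or voom (0.368), without the 3 libraries with over 20% intergenic fragments (0.0903), and with only these 2 groups fitted (adjusted p of 1). At an unadjusted p under 0.05 there were 199 genes, 110 higher and 89 lower, voom called 4, and 6.89% of genes did not overlap, where chance gives 9.59%. Besides mt-Nd6, the genes with the smallest p that did not pass were Tmem186 and Tm4sf5 (higher with cymopol) and Pradc1, Immp2l and Fndc4 (lower).

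Between the low doses of the agents, which also differ in units, limma called 0 genes, with 388 at an unadjusted p under 0.05 and 0 by voom. None of the 46 lists passed camera. The smallest p belonged to Htra2, Rarres2 and Thumpd3 (higher with cymopol) and to Tma7, Fahd2a and Wdfy1 (lower). Htra2, a mitochondrial protease, had 6.05, 2.67 and 5.85 FPKM in the cymopol low dose and was listed at 0 in the other 12 libraries (adjusted p = 0.375).

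Between the doses of the extract, the high dose had higher NRF2, tight junction and respiratory chain genes and lower fat-related genes, relative to all genes. NRF2 targets had a mean log2 difference of 1.43, 0.51 above all genes (camera adjusted p = 0.0447). Of the members, 42 of 43 lay above 0, but the median of all genes was itself 0.89. Tight junction genes stood 0.99 above all genes (adjusted p = 0.0132) and oxidative phosphorylation genes 0.79 above (0.0125). Adipocyte markers had a mean of -0.56, that is -1.47 relative to all genes (adjusted p = 7.31e-07, and adjusted p = 0.981 with an estimated correlation). Fatty acid synthesis genes had a mean of 0.11 and a median of 0.03 but stood at -0.80 relative to all genes, so that the test has the other sign (adjusted p = 0.00258). These genes and the NRF2, tight junction and oxidative phosphorylation lists had adjusted p = 0.989 with an estimated correlation, and 0 members of these 4 lists or of the adipocyte markers passed. mt-Nd6 gave adjusted p = 0.00258 as a list of 1 gene, and adjusted p = 0.156 in the run with an estimated correlation, with 0, 57.4 and 9.34 FPKM in the low dose. Without extract low dose replicate 26, which had 23.5% of fragments in intergenic loci, the NRF2 (0.873), tight junction (0.271) and oxidative phosphorylation (0.512) calls ended. They also ended without extract high dose replicate 21 (0.493, 0.0765 and 0.211), and the first and second without replicate 25 (0.115 and 0.0537). Median-of-ratios scaling ended the NRF2 (0.828), tight junction (0.0805), oxidative phosphorylation (0.279) and mt-Nd6 (0.132) calls. The fit without the 3 libraries with over 20% intergenic fragments ended those of NRF2 (0.910), tight junction (0.273) and oxidative phosphorylation (0.579), voom those of NRF2 (0.218) and fatty acid synthesis (0.171), and quantile normalization that of mt-Nd6 (0.127). Of single genes limma called 1, Snord11 (adjusted p = 8.57e-05, 0.424 with only these 2 groups fitted and 0.964 with voom), with 839 at an unadjusted p under 0.05 and 2 by voom. The doses did not overlap for 21.0% of genes, 2409 higher and 10 lower, where chance gives 9.16% with differences in depth left out. The smallest p among the others belonged to Rnf215, Tnni1 and Immp2l (higher) and to Lrrc6, Chchd6 and mt-Nd6 (lower).

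Between the doses of cymopol, clock genes were lower in the high dose relative to all genes, with a mean of -0.24, that is -0.83 (adjusted p = 0.0109, and adjusted p = 0.969 with an estimated correlation). Nr1d1 had 0.934, 2.32 and 3.21 FPKM in the high dose and 8.69, 18.9 and 4.08 in the low dose, and 0 of the 16 members passed. Fragments in genes made up 65.2% to 65.5% of the high dose libraries and 44.5%, 48.2% and 71.7% of low dose replicates 33, 34 and 35. This call ended without cymopol low dose replicate 34 (0.139) or 35 (0.0870), and with voom (0.761). NRF2 targets gave adjusted p = 0.459, with a mean 0.34 above all genes. The limma test called Gm11973 (adjusted p = 0.0321), listed at 0 in the low dose. That call ended without cymopol high dose replicate 12 (0.0603) or cymopol low dose replicates 33 (0.161), 34 (0.0805) or 35 (0.161). It also ended with a pseudocount of 0.1 (0.163), without the filter (0.185), with median-of-ratios scaling (1), quantile normalization (0.656), array weights (0.10) or voom (0.483), without the 3 libraries with over 20% intergenic fragments (0.141), and with only the 2 groups fitted (0.750). Called genes numbered 3 without cymopol high dose replicate 11, 2 without replicate 14, 2 without cymopol low dose replicate 34 and 0 without replicate 12 or 35. At an unadjusted p under 0.05 there were 671 genes, voom called 4, and 10.6% of genes did not overlap, where chance gives 9.17%. The smallest p among the others belonged to Hmox2, Smim8 and Tmem186 (higher) and to Htra2, Lrrc6 and Cd68 (lower).

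The 4 treated groups share the 3 vehicle libraries, so their differences from the vehicle are correlated by construction. Across genes, the correlation of log2 differences averaged 0.68 over the 6 pairs of treated groups, against 0.67 for simulated groups without change. It was 0.795 for the pair of high doses against 0.747 simulated (SD over simulations 0.00598), with a covariance of 0.930 against 0.890. For the pair of low doses it was 0.636 against 0.594 (SD 0.00752), with a covariance of 0.658 against 0.889. The other 4 pairs also had covariances below the simulated ones. The simulated groups share the vehicle libraries but leave out differences in depth between libraries. With 3 vehicle libraries the controls cannot be split, and part of any excess may come from them. Called genes shared between the high doses numbered 0, out of lists of only 2 and 1. The voom fit called 121 and 140 and shared 48, where simulated groups without change shared 50.4 (SD 5.24) and independent lists would share 1.47. At an unadjusted p under 0.05 the high doses shared 616 higher genes, fewer than the 749 (SD 14.3) shared by lists of the same sizes from simulated groups without change. They shared 57 lower genes against 45.9 (SD 3.51) simulated. Lists independent of each other would share 151 and 0.885, a value that leaves out the shared vehicle libraries.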

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

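The comparisons were planned, as were the fits with median-of-ratios scaling, with an estimated correlation and without each library, but using these and the other tests to weigh the 3 patterns here was chosen only after the results were seen. The results listed first were singled out because the effects of the high doses differed from each other in a direct test (cymopol high dose against extract high dose, 3 libraries each). NRF2 targets had a mean log2 difference of -0.41 (camera adjusted p = 0.00176), fatty acid synthesis genes 1.16 (7.85e-05), fibroblast and matrix genes 0.77 (0.00454) and adipocyte markers 1.94 (4.55e-09). None of the 4 passed with an estimated correlation, with adjusted p of 0.966 for the first 3 and 0.552 for adipocyte markers. On the log2(FPKM + 1) scale, the means of Snord11 differed by -6.29 and those of Gm11973 by 4.36. As each was listed at 0 in all libraries of one of the groups, these last 2 values depend on the pseudocount and are no bound on a fold change.

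NRF2 targets were higher in the extract high dose than in the vehicle, by a mean log2 difference of 1.95. The tables argue against the scaling of the FPKM values as the whole cause, since camera with its preset correlation gave an adjusted p of 2.83e-05 after median-of-ratios scaling, at a mean of 1.18. With an estimated correlation the list did not pass before (0.906) or after this scaling (0.274). No single vehicle library accounts for it either, since the highest adjusted p on leaving out each of them was 0.00423. Library depth and quality stay open, because the vehicle libraries had a lower share of fragments in genes. The cymopol high dose libraries, nearer in depth and quality than the vehicle, had scores of -0.37 to 0.20 against 0.06 to 0.84 for the extract and -1.06 to -0.05 for the vehicle, a mean difference of 0.536 between the high doses with overlapping ranges, so activation by the extract remains a hypothesis.

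Adipocyte markers were higher in the cymopol high dose than in the extract high dose, in 11 of 11 markers, and camera passed after median-of-ratios scaling (adjusted p = 1.54e-10), which argues against scaling as the cause. With an estimated correlation it did not pass, before (0.552) or after this scaling (0.0690). A candidate explanation is a varying share of fat tissue attached to the sample. Within groups the markers went up and down together, with a mean correlation of 0.553 after removing group means, above 99.33% of matched lists, whose median was 0.355. Markers of 1 cell type can move together whatever the cause, and the matched lists were random genes. This correlation therefore cannot tell attached fat tissue from other causes. Scores also spread within other groups, at -0.22, 0.89 and -1.17 in the vehicle, 0.51, -0.39 and 1.12 in the cymopol low dose and -0.13, 0.12 and 1.38 in the extract low dose. Whether the agents acted on fat cells was not tested and stays open.

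Relative to all genes, lymphocyte genes were lower in both high doses than in the vehicle, and MHC class II genes in the extract high dose. Without vehicle replicate 4, none of the 3 lists passed in either high dose, with a lowest adjusted p of 0.0845, so lymphoid tissue in that 1 library is a candidate explanation. For B and plasma cells the mean relative to all genes went from -1.99 (SD over members 0.701) to -0.87 (0.405) with cymopol and from -2.35 (0.797) to -1.23 (0.260) with the extract, for T and NK cells from -1.40 (0.681) to -0.59 (0.855) and from -1.90 (0.281) to -1.09 (0.732), and for MHC class II with the extract from -2.15 (0.346) to -0.75 (0.426). With cymopol, where MHC class II had not passed (adjusted p = 0.0852), it went from -1.11 (0.698) to 0.29 (0.654), the other direction. The calls ended through smaller differences and through fewer vehicle libraries alike. For the high values of that library the tables argue against library depth, since its B and plasma cell score was 1.97 above the highest of the other 14 (3.82 against 1.85) at a depth within that of the high doses. Its quality stays open, since 34.0% of its fragments lay in genes, a difference of -22.9 percentage points from the lowest high dose library. A lower share of lymphocytes after treatment was not excluded.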

How the results depend on the processing

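The voom fit, the fit without the 3 libraries with over 20% intergenic fragments, the added exonic pieces, the pairing of median-of-ratios scaling with an estimated correlation, the fit without genes with wide intervals, and the other settings for the similarity of treated groups were chosen after seeing the data. Counts of called genes are given in the order cymopol high, extract high, cymopol low and extract low dose against the vehicle, where the reported counts are 2, 1, 0 and 0. They were 7, 3, 0 and 1 with a pseudocount of 0.1, 1, 6, 0 and 0 without the filter, 0, 3, 2 and 1 with median-of-ratios scaling, 3, 2, 2 and 0 with quantile normalization, 0, 0, 0 and 0 in fits of only the 2 groups, 121, 140, 0 and 0 with voom, and 162, 206, 350 and 251 without the 3 libraries, which leaves 1 vehicle library, assumed to vary like the others. The last were mostly lower (152, 199, 345 and 246), unlike the genes at an unadjusted p under 0.05 in the high doses. Leaving out each library gave 0 to 8, 1 to 8, 0 to 9 and 0 to 8. For cymopol high against low dose (1 reported) the counts were 0 with a pseudocount of 0.1, either scaling, array weights, only the 2 groups and without the 3 libraries, 4 without the filter, 4 with voom and 0 to 3 on leaving out libraries. The extract doses (1 reported) gave 3 without the filter, 13 with array weights, 0 with only the 2 groups and 2 with voom, and the high doses against each other (2 reported) gave 1 with a pseudocount of 0.1 or either scaling, 9 without the filter, 7 with array weights, 4 with voom and 1 to 3 on leaving out libraries. The low doses against each other gave 0 in every setting run. The NRF2 mean log2 difference from the vehicle kept its sign in every setting run, in all 4 groups. For the cymopol high dose the call was lost at 2.58 (pseudocount 0.1, adjusted p = 0.119), 0.65 (median-of-ratios scaling, 0.0668, and 0.636 with an estimated correlation), 1.45 (array weights, 0.0587), 1.49 (without genes with wide intervals, 0.0685) and 1.54 (estimated correlation, 0.991), and leaving out libraries gave 1.08 to 1.78. For the extract high dose the estimated correlation ended it at 1.95 (0.906), and at 1.18 with median-of-ratios scaling (0.274), and for the extract low dose at 0.52 (0.987) and 0.74 (0.670). Leaving out libraries gave 1.49 to 2.19 and 0.040 to 1.43 there. For the cymopol low dose the list passed without the filter at 0.59 (0.0439), with 0.06 to 1.18 on leaving out libraries. Lists called fell from 34 to 1 (mt-Nd6, a list of 1 gene with no correlation to estimate) with an estimated correlation and 28 with median-of-ratios scaling, and rose to 51 with quantile normalization, 52 with voom and 41 without the 3 libraries. The mean correlation of 0.68 between treated groups became 0.62 with voom and 0.87 without the 3 libraries, and 0.62 to 0.78 on leaving out libraries. It rose to 0.783, 0.726 and 0.755 without vehicle replicates 2, 4 and 5, and fell without any treated library. A rise is built into fits with fewer vehicle libraries, whose error the treated groups share. The cause of the change with voom was not tested. Of 3360 values of named genes under alternatives, 2928 stayed on their side of the threshold or within the spread, 290 moved, 47 lost and 95 gained a call, 0 reversed after a call, and 75 changed sign. The libraries held 25233 to 556461 fragments in protein-coding genes, and many genes are listed at 0, which limits the changes that can be detected. The share listed at 0 did not follow depth alone. It was 27.1% of tested genes in vehicle replicate 4 at 226553 fragments, and 13.1% in extract high dose replicate 21 at 174939.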

Other observations

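The splits of the libraries were planned, and the lists below were fixed before the data were examined, while the genes and comparisons picked from them here were chosen after seeing the values. Single markers of absorptive and hormone-producing epithelium passed adjusted over their lists alone in the high doses, in lists that did not pass. Surface colonocyte genes had a mean 1.16 above all genes in the cymopol high dose against the vehicle (14 genes, camera adjusted p = 0.0548), and small intestine genes 1.75 above (4 genes, 0.0714). Guca2b, which encodes uroguanylin, had 7.30, 4.41 and 116 FPKM in the cymopol high dose and was listed at 0 in the vehicle (adjusted p over the list alone 0.0153, over all genes 0.190). Pyy, a hormone of enteroendocrine cells, had 30.2, 55.0 and 22.5 FPKM and Rbp2, a retinol-binding protein of enterocytes, 14.4, 7.36 and 42.1, both listed at 0 in the vehicle and past the threshold adjusted over the list alone (0.00389 and 0.00284). In the extract high dose Pyy had 1.24, 165 and 8.63 FPKM (0.0467) and Rbp2 8.58, 36.0 and 9.04 (0.00485). The enteroendocrine list had its smallest adjusted p of 0.346 in the extract high dose, 0.70 above all genes. Cd68, a macrophage marker, had 7.33, 11.6 and 5.56 FPKM in the cymopol low dose against 0, 0.847 and 0 in the vehicle (adjusted over the list alone 0.00723, over all genes 0.487), while the macrophage and dendritic cell list reached 0.257 at its smallest, in the extract high dose. These epithelial values moved with the share of fragments in genes, which was at most 46.5% in the vehicle and at least 56.9% in the high doses.

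Stress and drug metabolism lists did not pass in any comparison, and each is given at its smallest camera adjusted p. Against the vehicle, unfolded protein response genes stood 0.66 above all genes in the extract high dose (0.0554), hypoxia and glycolysis genes 0.50 above there (0.401), ATF4 targets 0.50 above in the cymopol high dose (0.107), cholesterol synthesis genes 0.45 above there (0.204) and heat shock genes 0.34 above in the cymopol low dose (0.459). Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, had 5.15, 8.13 and 9.87 FPKM in the cymopol high dose and 10.3, 6.13 and 4.31 in the extract high dose, and was listed at 0 in the vehicle (adjusted over the list alone 0.0263 and 0.0442, over all genes 0.210 and 0.291). Asns, asparagine synthetase, had 6.37, 5.08 and 3.91 FPKM in the cymopol high dose and was listed at 0 in the vehicle (adjusted over the list alone 0.0420). Between the high doses, CAR and PXR targets stood at -0.49 relative to all genes (0.149), AHR targets, of which only Tiparp was measured, at -1.29 (0.242), interferon response genes at -0.31 (0.496) and PPAR alpha targets at -0.16 (0.715). p53 targets (0.106) and conjugating enzymes (0.550) were lowest in p between the extract doses, at 0.54 and 0.29 above all genes. Inflammatory mediators, with 2 of 22 genes measured, had 0.597 in the cymopol low dose against the vehicle.

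The remaining lists are given in the same way. Replication histones had 0.0865 and proliferation genes 0.340 in the cymopol high dose against the vehicle, at 0.96 and 0.15 above all genes. Smooth muscle genes had 0.141 and enteric neuron and glia genes 0.485 in the cymopol low dose against the vehicle, at 0.75 and 0.30 above. In the extract low dose against the vehicle, tuft cell genes stood at -0.97 (0.213) and nuclear and small noncoding RNA at 0.50 (0.574). Erythroid genes stood at -1.36 (0.0626), distal Hox genes at -0.75 (0.355) and crypt stem cell genes at 0.30 (0.574) in the cymopol high against low dose, and endothelial genes at 0.47 (0.149) between the high doses. Between the low doses, glucocorticoid targets stood at 0.86 (0.168), immediate early genes at 0.48 (0.367) and antimicrobial defence genes at 0.79 (0.629). The lists of neutrophils (0.367), mast cells (0.508), pancreatic acinar cells (0.209) and squamous epithelium (0.346) had 1 measured gene each.

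Splits of the 6 libraries of a comparison into 3 and 3 number 10, so the share of splits with a result as large is never under 0.05. The real split called 2 genes and the highest other split 1 for the cymopol high dose against the vehicle, 0 and 3 for the cymopol low dose, 1 and 2 for the extract high dose, and 0 and 12 for the extract low dose. The counts were 1 and 1 between the cymopol doses, 1 and 6 between the extract doses, 2 and 1 between the high doses and 0 and 2 between the low doses. Splits with at least the real count numbered 1, 10, 3, 10, 3, 3, 1 and 10 in this order. A split that called 12 genes where the real one called 0, and one that called 6 where the real one called 1, may reflect some structure of the samples, which was not tested. The NRF2 mean relative to all genes was 0.71 in the real split and 0.79 in the highest other for the cymopol high dose, 0.37 and 0.74 for the cymopol low dose, 1.22 and 1.01 for the extract high dose and 0.71 and 1.13 for the extract low dose. Splits at least as far apart numbered 2, 4, 1 and 3.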
